A study of Mus musculus with 6 samples.

How the data were processed

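Small RNA was profiled in hearts of 3 control and 3 knockout mice, and each mouse gave 1 library in the table. Per the labels' protocols, total RNA was isolated from whole hearts, and small RNA libraries were size-selected for 15 to 100 nt and sequenced in paired ends. The series' design text states 4 technical replicates per mouse, and how they were merged is not given in the sources used here. Groups and replicate numbers came from the sample titles (L/L and L/L, cre). The labels give control mice the genotype Elac2 +/+, while the titles describe floxed alleles.

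The authors deposited raw counts per feature for each mouse, as whole numbers. The authors also deposited normalized counts (a signal that is the raw count divided by 1 size factor per mouse, as found from the values) and a table of their own comparison with log2 fold changes, p-values, adjusted p-values and a Wald score per feature, per the file headers. Per the submitters' processing notes, cutadapt 1.14, Bowtie2 2.2.9, featureCounts 1.5.1 and DESeq2 1.16.1 were used with genome build mm10. The annotation, the strand setting and the handling of reads with several alignments are not given in the sources used here. Counts of near-identical copies, such as tRNA genes, miRNA copies and pseudogenes, and of genes that overlap on either strand are therefore uncertain. The counts were the input of every test, and the normalized counts served only for the comparison of size factors. There were 0 columns of other samples.

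The table held 30638 features, of which 21384 had 0 counts in every library. Of 29863 Ensembl gene IDs, 29738 matched GENCODE M21 (GRCm38, mm10), which gave positions and strands. Symbols and RNA classes came from the gene names and gene types in the authors' deposited comparison. The names in the table gave 268 mature tRNAs, 471 precursor tRNAs and 36 mitochondrial features, in which Atp8 with Atp6 and Nd4l with Nd4 are joined. Positions of nuclear tRNA features were not used here. The table held 2207 miRNA, 1508 snoRNA, 51 scaRNA and 8281 processed pseudogene features and 0 nuclear protein-coding ones.

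Features were kept by edgeR's filterByExpr (minimum count 10, minimum total 15, by group), which left 1144 features holding at least 99.89% of the counts of each library. Library sizes were scaled by TMM factors (1.14, 1.09 and 1.15 in control and 0.949, 0.828 and 0.889 in knockout replicates 1 to 3). Knockout was tested against control with edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3) with no covariate, a Benjamini-Hochberg adjusted p under 0.05 was called, and the biological coefficient of variation was 0.217. Every adjusted p given for a single gene is from this fit unless another tool is named. Values are TMM-scaled counts per library size (CPM, with library sizes in units of 1e6), and log2 CPM for list tests used a prior count of 2. Shares of counts per class were compared with exact two-sided permutation tests of the difference in means. Gene lists with at least 3 tested members were tested with limma 3.58.1 (camera on log2 CPM, preset correlation 0.01, with an estimated correlation beside it), adjusted over 20 lists, and fry was run on the same lists. Of the 20 lists, 13 passed with the preset correlation and 13 by fry. With an estimated correlation 0 passed by limma's camera, 1 had an unadjusted p under 0.05 and the lowest adjusted p was 0.122. Camera compares a list with the other genes, and fry's directional test asks whether the genes of a list move on balance one way. Pseudogenes were compared with mitochondrial genes and protein-coding transcripts by BLASTN 2.17.0 (at least 30 nt at 90% identity). Tables and figures used Python 3.11.15, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

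The groups, tests, alternatives, gene lists and the rule for named genes were set before the data were examined. The rule took up to 2 genes per direction and RNA class (4 for miRNAs) with the largest change among called genes with at least 10 CPM in a group and no overlap between the groups. It added the 2 most abundant tested members of each list, Elac2, and Malat1, Nppa, Nppb, Mir21a, Mir208a and Mir208b where tested. Genes named outside the rule are marked as such. The lists covered mitochondrial tRNAs of each strand, mitochondrial mRNA and rRNA, striated muscle, cardiac stress, antifibrotic, let-7, Dlk1-Dio3, endothelial, blood and immune, and smooth muscle and fibroblast miRNAs. Further lists were RNA polymerase III transcripts, lncRNAs with a tRNA-like 3′ end, the RNA classes, and 6 mRNA lists with 0 measured members.

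Libraries were distinct: the lowest chi-square per degree of freedom between 2 libraries was 79.1. Log2 fold changes had a Pearson r of 0.998 across genes with those in the authors' deposited table, in which 763 of 2597 features with an adjusted p were called, 228 higher and 535 lower. Of the genes tested here, 462 were called in the authors' deposited table and 452 in both, all 452 with the same sign. The test was run first on counts simulated for 1089 genes in this comparison. It recovered 21.0% of genes changed 1.5-fold, 55.6% of those changed 2-fold and 96.7% of those changed 4-fold, and called 0.886% of unchanged genes. Of the 1089 simulated genes 903 were unchanged, and rises and falls were set about equal in number. In the real data whole RNA classes moved one way, so these rates need not hold there. The 1 changed list was called and 0 of 20 random lists were. Replicates of a group differed far beyond counting error, so the spread between mice limits the precision. No molecular identifiers of the reads are given in the sources used here.

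Alternatives were DESeq2 size factors, total counts alone, TMM factors from miRNA genes or from snoRNA and scaRNA genes, no filter on low counts, DESeq2 1.42.0 (Wald test), limma-voom, the replicate number as a block, glmTreat against a fold change of 1.5, tRNA counts summed per anticodon, other denominators for the shares, and leaving out each library in turn. TMM factors from snRNA and nuclear rRNA genes were added after the data were seen, because the planned scalings all moved values downward.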

Results

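Small RNA reads were counted in hearts of 6 C57BL/6 mice, from libraries built on inserts of 15 to 100 nt. The 3 control mice are labelled L/L, with loxP sites around an Elac2 exon and no cre. The 3 knockout mice are labelled L/L, cre, with that exon removed by a cre recombinase under a muscle creatine kinase promoter. Elac2 encodes RNase Z, the enzyme that cuts the 3′ trailer off precursor tRNAs in the nucleus and in mitochondria. The comparison asked how its loss changes the non-coding RNAs of both compartments. Total counts were 13510061, 16248673 and 15951770 in control replicates 1 to 3 and 14505705, 15271036 and 14947237 in knockout replicates 1 to 3. Control libraries had 4664, 6018 and 5845 features with at least 1 count, and knockout libraries had 3160, 3095 and 2995. Elac2 mRNA was not analysed here, so the genotype labels could not be checked by the targeted gene. Nuclear mRNAs were not analysed either, and the 6 mRNA lists fixed beforehand (cardiac fetal genes, mitochondrial stress response, cardiomyocyte, matrix and fibroblast, endothelial, blood and immune) each had 0 measured members.

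Small nucleolar RNAs, which guide chemical modification of ribosomal RNA, took up more of the knockout libraries, while mitochondrial RNAs and mature nuclear tRNAs took up less. The share of counts in snoRNA and scaRNA genes was 41.0% ± 1.65 (SD, n = 3) in control and 62.9% ± 1.21 (SD, n = 3) in knockout hearts. The miRNA share was 41.6% ± 1.99 against 31.4% ± 2.08. Mitochondrial tRNAs held 5.70% ± 1.83 of control counts and 0.483% ± 0.0586 of knockout counts, 11.8 times less. Fragments of mitochondrial mRNAs held 1.53% ± 0.658 against 0.0849% ± 0.0173, and mitochondrial rRNAs 0.912% ± 0.141 against 0.464% ± 0.0458. Mature nuclear tRNAs held 3.34% ± 0.569 against 0.452% ± 0.103, while precursor tRNAs, still carrying leader, trailer or intron sequence, held 0.0367% ± 0.00549 against 0.0503% ± 0.00576. The misc_RNA class, which holds 7SK and Y RNAs, went from 0.496% ± 0.136 to 0.0658% ± 0.00708, and processed pseudogenes from 0.0795% ± 0.0341 to 0.00601% ± 0.000902. Every knockout library lay on one side of every control library for each of these classes, which gave p = 0.1 in exact two-sided permutation tests, the smallest p that 3 against 3 allow. The mitochondrial 7S RNA (0.419% against 0.379%, exact p = 0.4), lincRNA (3.25% against 2.14%, exact p = 0.2) and ribozyme shares (0.0501% against 0.0522%, exact p = 0.7, n = 3 per group) overlapped between the groups. Control replicate 1 stood apart from the other control libraries in some of these classes, with 3.70% mitochondrial tRNA against 7.28% and 6.13%, 0.812% mitochondrial mRNA against 2.11% and 1.67%, and 0.0402% processed pseudogenes against 0.10% and 0.0979%.

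**Figure D1:**
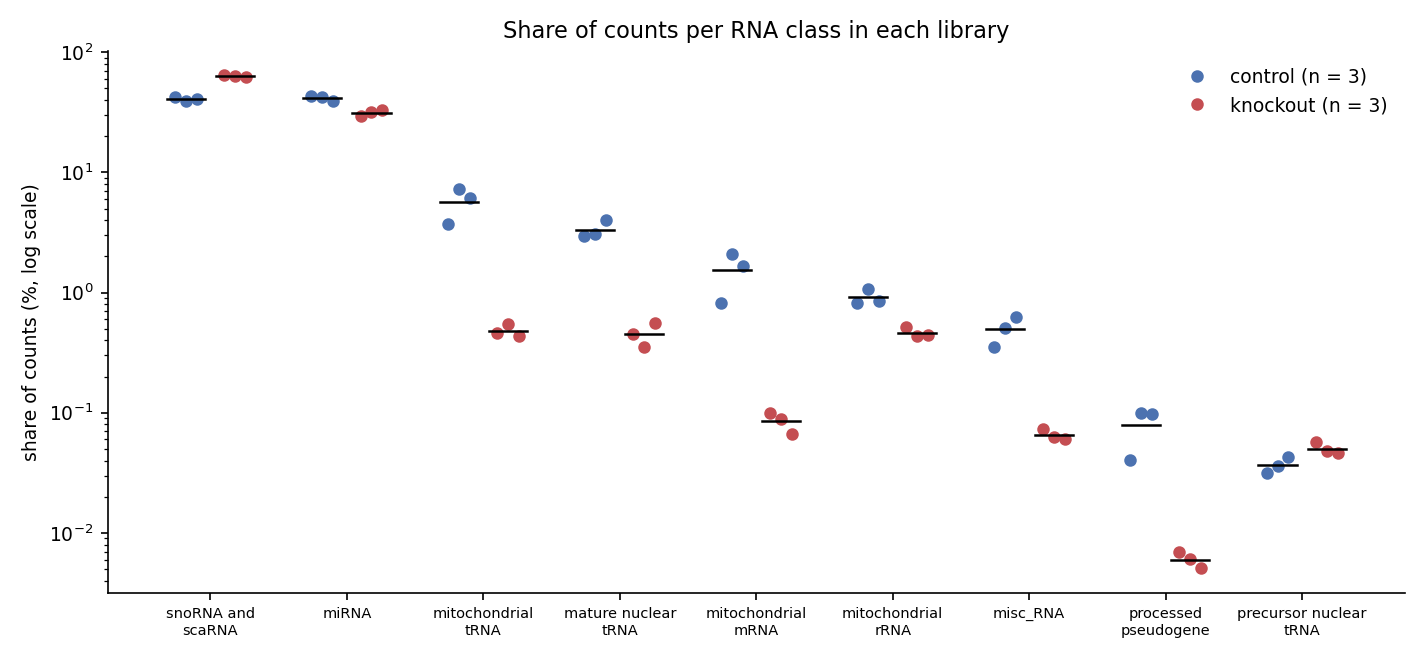
Share of counts (percent, log scale) in 9 RNA classes for each control and knockout library (points, n = 3 per group), with the group mean as a line. The snoRNA and scaRNA share rose from a mean of 41.0% to 62.9% of the counts within a library, while the mitochondrial tRNA share fell from 5.70% to 0.483%.

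Of 1144 features tested, 574 changed between knockout and control hearts by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 265 higher and 309 lower in knockout hearts. The 4 other library scalings planned all moved values downward, and 101 of the 265 higher calls were made in all of them. Factors from snRNA and nuclear rRNA genes, chosen after the data were seen, moved the median log2 fold change by 0.55, and 224 of the 309 lower calls were made with them. The median log2 fold change over all genes moved by -0.34 with total counts alone, by -0.18 with factors from miRNA genes and by -0.84 with factors from snoRNA and scaRNA genes. The share of higher calls was 46.2%, 28.2%, 34.8% and 13.3% from the main scaling to the snoRNA-based one, and 64.6% with factors from snRNA and rRNA genes. Groups did not overlap for 721 of the 1144 features (63.0%), where chance gives 10%. Without control replicate 1, 1410 features were tested and 908 were called. Leaving out knockout replicate 1, 2 or 3 shifted log2 fold changes upward over all genes, by a median of 0.21, 0.24 and 0.22, with 1403, 1389 and 1405 features tested. Without control replicates 1 to 3 the shifts were 0.0168, -0.012 and -0.0244. Calls lost or gained without a knockout library therefore cannot be put down to a single mouse alone.

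Reads of all 22 mitochondrial tRNAs fell in knockout hearts, with log2 fold changes from -6.89 to -1.03 and a median of -3.43. Libraries held inserts of 15 to 100 nt, so fewer reads cannot tell less tRNA from tRNA left in longer transcripts. The tRNA for asparagine, mt-Tn, fell most in reads: it went from 4990 ± 157 CPM (scaled counts; SD, n = 3) to 41.9 ± 18.9, a log2 fold change of -6.89 (SE 0.37, adjusted p = 2.55e-07, 119 times lower). The glutamate tRNA mt-Te went from 1422 ± 511 to 31.5 ± 6.96 CPM (log2 fold change -5.50, SE 0.33, adjusted p = 4.51e-07). The most abundant mitochondrial tRNA in control hearts, the serine tRNA mt-Ts2, went from 24724 ± 10172 to 1773 ± 381 CPM (log2 fold change -3.80, SE 0.30), and its neighbour mt-Th, the histidine tRNA, from 9404 ± 3809 to 2339 ± 591 CPM (log2 fold change -2.01, SE 0.29). Among the 14 tRNAs of the heavy strand the median log2 fold change was -2.88, and among the 8 of the light strand it was -4.54. All 14 and all 8 also passed when adjusted over the list alone. By camera with a preset correlation, both lists stood below the other genes (adjusted p = 7.04e-06 for each list), with adjusted p = 0.442 with an estimated correlation for each. The 22 tRNAs tested as a class gave adjusted p = 7.93e-10 by camera and adjusted p = 0.442 with an estimated correlation. The 22 calls were made under the 4 planned scalings and with each library left out. With factors from snRNA and rRNA genes 20 were made, and mt-Ti and mt-Tv were not called. The gene mt-Ts2 (chromosome M, positions 11613 to 11671 in GRCm38) shares its last base with mt-Tl2.

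Mitochondrial mRNA and rRNA genes, whose transcripts are separated by tRNAs, also fell: all 13 were called lower, and all 13 when adjusted over the list alone, with a median log2 fold change of -3.65. Reads from mt-Co1, a subunit of cytochrome c oxidase, went from 4050 ± 1954 to 147 ± 44.1 CPM (SD, n = 3; log2 fold change -4.78, SE 0.40, adjusted p = 3.23e-06). Reads from mt-Nd6, the complex I subunit encoded on the light strand, went from 112 ± 34.0 to 4.41 ± 1.45 CPM (log2 fold change -4.66, SE 0.33, adjusted p = 1.08e-06). Log2 fold changes of the 11 mRNA features lay between -4.78 and -2.21, and the ribosomal RNAs moved less. The 16S rRNA gene mt-Rnr2 went from 7169 ± 1266 to 4661 ± 209 CPM (log2 fold change -0.62, SE 0.15, adjusted p = 0.00455), and the 12S rRNA gene mt-Rnr1, named after its values were seen, from 957 ± 214 to 560 ± 95.1 CPM (log2 fold change -0.77, SE 0.20, adjusted p = 0.00739). The mitochondrial 7S RNA, mt-7s, was not called and was also named after its values were seen (log2 fold change 0.19, SE 0.16, adjusted p = 0.328, but -0.66 and adjusted p = 0.00436 with snoRNA-based factors, and 0.71 and adjusted p = 0.0385 with factors from snRNA and rRNA genes). As a list the 13 genes gave adjusted p = 4.63e-06 by camera and adjusted p = 0.442 with an estimated correlation. The call of mt-Rnr2 was lost without knockout replicate 1 (log2 fold change -0.43, adjusted p = 0.0960), 2 (-0.36, adjusted p = 0.226) or 3 (-0.39, adjusted p = 0.157), and that of mt-Rnr1 without knockout replicate 1 (-0.54, adjusted p = 0.0617) or 3 (-0.45, adjusted p = 0.112). Without a filter on low counts both calls were lost (adjusted p = 0.554 for mt-Rnr2 and 0.265 for mt-Rnr1). They were also lost with factors from snRNA and rRNA genes (-0.07 and -0.23), where the 11 mRNA features kept theirs. Reads of mt-Co1 and mt-Nd6 are uncertain where mt-Ts1 and mt-Nd5 overlap them on the opposite strand, since the strand setting of the counting was not given in the sources used here. Control replicate 1 had 2002 CPM of mt-Co1, against 5895 and 4252 in the other control libraries.

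**Figure D2:**
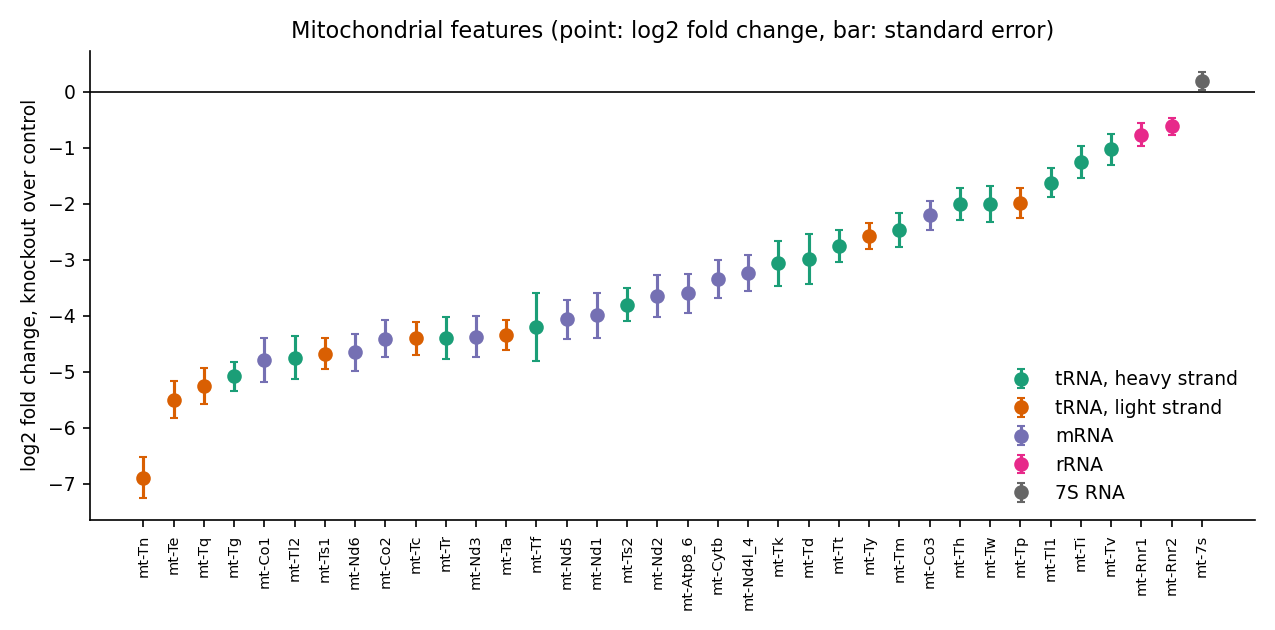
Log2 fold change (knockout over control, 3 hearts per group) of each mitochondrial feature, sorted, with bars for the standard error and colours for the kind of RNA and the tRNA strand. The 22 tRNAs lie between -6.89 and -1.03 and the 11 mRNA features between -4.78 and -2.21, below 0 under each scaling tried, while mt-7s lies at 0.19, not called, and at -0.66 with snoRNA-based factors.

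More mature nuclear tRNA features fell than rose in reads: of 124 tested, 48 fell and 15 rose, with a median log2 fold change of -0.45. With factors from snRNA and rRNA genes this balance was reversed, with 26 lower, 30 higher and a median of 0.09. Inserts of 15 to 100 nt can hold whole tRNAs or fragments of them, which the counts do not tell apart. The reads therefore do not measure the amount of intact mature tRNA. The mature glycine tRNA Gly-GCC-5 went from 990 ± 258 to 43.2 ± 2.69 CPM (SD, n = 3; log2 fold change -4.52, SE 0.24, adjusted p = 2.55e-07). The mature glutamate tRNA Glu-CTC-1 went from 5515 ± 1216 to 282 ± 86.6 CPM (log2 fold change -4.29, SE 0.27, adjusted p = 5.52e-07). Precursor tRNAs, the substrate of RNase Z, more often went the other way. Of 114 tested, 43 rose, 14 fell and 57 were not called, with a median log2 fold change of 0.21. The precursor of the aspartate tRNA Asp-GTC-1-11 went from 1.41 ± 0.145 to 111 ± 23.9 CPM (log2 fold change 6.28, SE 0.27, adjusted p = 1.02e-07, 77.7 times higher). The precursor of the tyrosine tRNA Tyr-GTA-1-1 went from 0.188 ± 0.111 to 14.5 ± 4.03 CPM (log2 fold change 6.17, SE 0.42, adjusted p = 7.23e-07). Their lowest log2 fold changes under 4 other scalings were 5.44 and 5.35. The precursor median turned negative with total counts alone (-0.13) and with snoRNA-based factors (-0.64), and the mature median turned positive without a filter on low counts (0.30; 32 lower and 26 higher). In the same order as for all genes, the share of higher calls among precursors was 75.4%, 61.3%, 70.7% and 41.5% across the scalings, 82.0% with factors from snRNA and rRNA genes and 92.2% without a filter. Without a filter 106 of 338 precursors rose and 9 fell, with a median of 1.42. Among mature forms it was 23.8%, 13.9%, 15.9%, 9.89%, 53.6% and 44.8% in the same order, and among all 238 nuclear tRNAs 48.3%, 35.8%, 42.1%, 24.9%, 68.4% and 76.3%. Of the 43 higher precursor calls 34 were made in all 4 planned scalings. With factors from snRNA and rRNA genes 26 of the 48 lower mature calls were made, Gly-GCC-5 and Glu-CTC-1 included. As classes, precursors stood above the other genes by camera (adjusted p = 0.00199, and adjusted p = 0.442 with an estimated correlation). Mature tRNAs stood below them (adjusted p = 0.0337, and adjusted p = 0.442 with an estimated correlation), a call lost without control replicate 1 (adjusted p = 0.0897). Adjusted over each class alone, the counts were 43 and 14 for precursors and 15 and 48 for mature forms. Most precursors were rare: of the 9 with a mean of at least 10 CPM, 2 rose and 3 fell. Without control replicate 1, 144 precursors were tested, of which 64 rose and 24 fell. With more precursors tested, their median was 0.441, 0.642 and 0.793 without control replicates 1 to 3 and 0.421, 0.515 and 0.497 without knockout replicates 1 to 3. The mature median was -0.384, -0.424 and -0.444 without control replicates 1 to 3 and -0.216, -0.203 and -0.254 without knockout replicates 1 to 3.

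Copies of a tRNA gene are nearly identical and single features are therefore uncertain, so counts were also summed per anticodon within each form. Reads shared between mature and precursor features are not settled by these sums. Aspartate GTC showed the widest split: its mature form fell by 2.06 on the log2 scale, from 107 to 25.6 CPM, while its precursors rose from 6.98 to 136 CPM (log2 fold change 4.28). Serine AGA (-0.79 mature and 2.92 precursor), serine CGA (-0.85 and 3.06) and valine TAC (-0.78 and 2.36) moved in the same opposed way. In all, 9 of 44 anticodons had a called rise of the precursor with a called fall of the mature form, and in 35 of 44 the precursor value lay above the mature one. Of 47 mature anticodons 23 fell and 5 rose, and of 45 precursor anticodons 21 rose and 4 fell. Glutamate CTC fell in both forms (-4.18 and -0.98), as did the selenocysteine tRNA (SeC-TCA, -0.93 and -3.56). Of the mature alanine tRNAs, TGC (log2 fold change 3.24) and AGC (2.69) rose and CGC fell (-0.64, adjusted p = 0.0376). The anticodons named here were chosen after their values were seen. Across anticodons, which are not independent replicates, the log2 fold changes of both forms had a Pearson r of 0.0804.

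**Figure D3:**
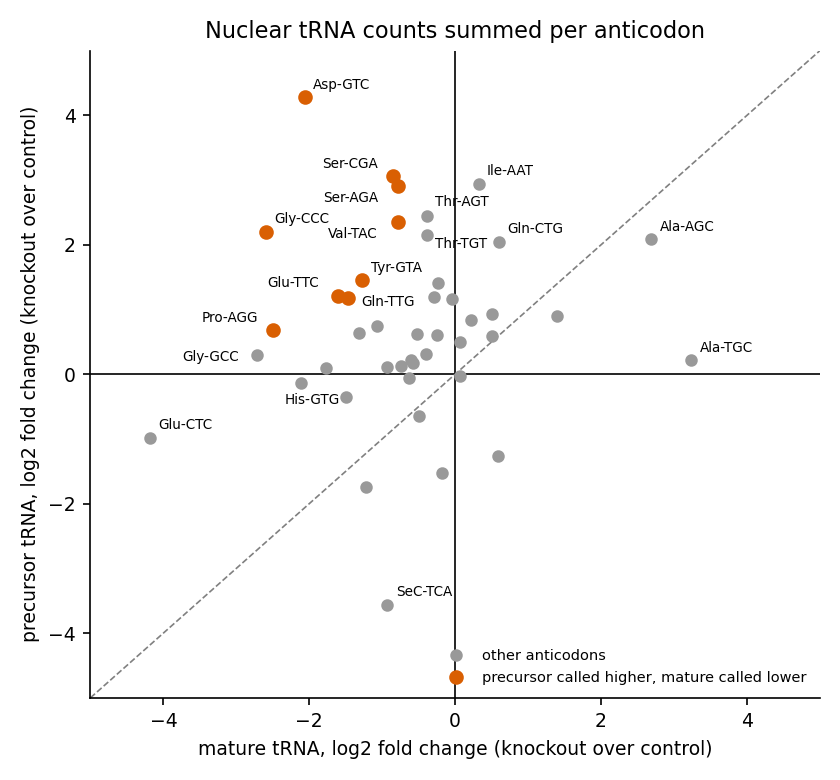
Log2 fold change (knockout over control, counts summed per anticodon, 3 hearts per group) of precursor tRNA against mature tRNA for 44 anticodons (points), with a dashed line where both are equal. In 9 anticodons, in orange, the precursor was called higher and the mature form lower, with aspartate GTC farthest out at -2.06 and 4.28; the median over single precursors turned negative with total counts alone (-0.13) and with snoRNA-based factors (-0.64).

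Of 85 genes named as box C/D snoRNAs, which guide 2′-O-methylation of ribosomal RNA, 63 rose and 0 fell in knockout hearts, also when adjusted over the list alone. Their median was 1.04 (camera adjusted p = 9.32e-14, and adjusted p = 0.122 with an estimated correlation). With snoRNA-based factors 22 of them rose and 14 fell, and with factors from snRNA and rRNA genes 72 rose and 0 fell. Of 253 snoRNA and scaRNA genes tested, 142 rose and 8 fell, with a median log2 fold change of 0.74 that turned to -0.11 when factors came from these genes themselves. Adjusted over the list alone the counts were also 142 and 8. The 8 lower calls became 4 without control replicate 3 and 4, 2 and 3 without knockout replicates 1, 2 and 3. Snord93 went from 11.1 ± 2.02 to 109 ± 3.95 CPM (SD, n = 3; log2 fold change 3.28, SE 0.21, adjusted p = 5.87e-07). Its near-copy Mir3096, annotated as a snoRNA, went from 2.94 ± 0.384 to 35.3 ± 3.08 CPM (log2 fold change 3.59, SE 0.23, adjusted p = 5.52e-07). These 2 genes differ at 1 of 71 positions, so the split of reads between them is uncertain, and their lowest log2 fold changes under 4 other scalings were 2.44 and 2.74. The host transcripts 1110038B12Rik (1195 ± 35.6 to 3691 ± 645 CPM, log2 fold change 1.63, SE 0.16, adjusted p = 1.03e-05) and Gas5 (852 ± 101 to 1948 ± 431 CPM, log2 fold change 1.19, SE 0.19, adjusted p = 0.000269) rose too. Both carry snoRNA genes in exons on the same strand, so their reads are uncertain. Among the 4 planned scalings Gas5 lost its call only with snoRNA-based factors (adjusted p = 0.109). Gm23262, annotated as a snoRNA gene, fell from 50.1 ± 10.5 to 23.3 ± 2.33 CPM (log2 fold change -1.11, SE 0.22, adjusted p = 0.00107). It overlaps an exon of Eif4g2 on the same strand, so its reads are uncertain. Gm24119 fell from 72.7 ± 3.66 to 50.2 ± 4.39 CPM (log2 fold change -0.54, SE 0.18, adjusted p = 0.0270). Gm23262 (168 nt) and Gm24119 (246 nt) are longer than the size window. The call of Gm24119 was lost without control replicate 1 (adjusted p = 0.0871) or 3 (0.0631) and without knockout replicate 1 (0.371), 2 (0.425) or 3 (0.157), and without a filter on low counts (0.576). With factors from snRNA and rRNA genes Gm23262 (-0.52, adjusted p = 0.0573) and Gm24119 (0.03) were not called, and 1 of the 8 lower calls was made. Among 24 H/ACA snoRNAs, which guide pseudouridylation, 8 rose and 0 fell (1 and 0 adjusted over the list alone; camera adjusted p = 0.0962), with a median of 0.45. With total counts alone 1 rose and 4 fell, with miRNA-based factors 1 and 1, and with snoRNA-based factors 0 and 7 (median -0.38). The factors from snRNA and rRNA genes gave 12 higher and 0 lower. Of 11 scaRNAs, the Cajal body guides of spliceosomal RNAs, edgeR called 0, with 0 at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom (camera adjusted p = 0.414), while snoRNA-based factors gave 8 lower and factors from snRNA and rRNA genes 3 higher. The share of higher calls among all snoRNAs and scaRNAs was 94.7%, 84.5%, 91.6% and 41.5% across the scalings in the order given above.

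Among called miRNA genes with at least 10 CPM in a group and no overlap between the groups, Mir708, in an intron of Tenm4, rose most. It went from 8.04 ± 3.46 to 139 ± 36.8 CPM (SD, n = 3; log2 fold change 4.12, SE 0.34, adjusted p = 3.06e-06, 17.4 times higher). Mir34a, a p53-induced miRNA linked to cardiac ageing, went from 8.79 ± 4.25 to 38.7 ± 10.5 CPM (log2 fold change 2.13, SE 0.34, adjusted p = 0.000307). Mir21a, a miRNA induced in stressed and fibrotic hearts, went from 3137 ± 42.7 to 9356 ± 1470 CPM (log2 fold change 1.58, SE 0.15, adjusted p = 6.76e-06). Mir1983 (log2 fold change 3.41, SE 0.24, adjusted p = 1.08e-06) and Mir7688 (4.61 ± 1.37 to 36.7 ± 3.59 CPM, adjusted p = 3.87e-06) rose as well. Positions of nuclear tRNA genes were not used here, so whether reads of Mir1983 or other miRNA genes come from tRNA transcripts was not checked. The lowest log2 fold change under 4 other scalings was 3.27 for Mir708, 2.57 for Mir1983, 2.15 for Mir7688, 1.31 for Mir34a and 0.73 for Mir21a. Mir30e, in an intron of Nfyc and overlapped on the other strand by Mir30f, fell from 2863 ± 232 to 1534 ± 114 CPM (log2 fold change -0.90, SE 0.15, adjusted p = 0.00031), and Mir1964 (-1.11, SE 0.23, adjusted p = 0.00171) and Mir149 (-0.82, SE 0.20, adjusted p = 0.00434) fell too. AC099934.1 (-1.52, SE 0.26, adjusted p = 0.000418) lies inside an exon of the 7SL gene Rn7s1, so its reads are uncertain. The call of Mir149 was lost without knockout replicate 1 (log2 fold change -0.54, adjusted p = 0.0918), and without a filter on low counts the calls of Mir149 (-0.48, adjusted p = 0.160) and Mir30e (-0.55, adjusted p = 0.0800) were lost. In total 53 of 312 miRNA genes rose and 20 fell (30 and 17 adjusted over the list alone), with a median of 0.21. That median was -0.13 with total counts alone and -0.63 with snoRNA-based factors. It was 0.287, 0.185 and 0.148 without control replicates 1 to 3 and 0.435, 0.439 and 0.346 without knockout replicates 1 to 3. The share of higher calls was 72.6%, 23.8%, 40.6% and 7.69% in the order given above, 96.8% with factors from snRNA and rRNA genes and 93.4% without a filter. Of the 53 higher calls 13 were made in all 4 planned scalings. Of the 20 lower calls 4 were made with factors from snRNA and rRNA genes, where Mir30e (-0.35), Mir1964 (-0.55) and Mir149 (-0.27) were not called. Without a filter 8 miRNAs were lower. The 53 higher calls became 85 without control replicate 1, 35 without control replicate 3, 88 without knockout replicate 1 and 85 without knockout replicate 2. The 20 lower calls became 7, 8 and 10 without knockout replicates 1, 2 and 3. As a class miRNAs stood above the other genes by camera (adjusted p = 0.00273, and adjusted p = 0.442 with an estimated correlation), a call lost with total counts alone (adjusted p = 0.0724).

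Among 15 miRNAs of a list on cardiac stress and remodelling, 9 rose and 0 fell (11 and 0 adjusted over the list alone), with a median log2 fold change of 0.75 that was -0.09 with snoRNA-based factors. Besides Mir21a and Mir34a, Mir199a-1, expressed in fibroblasts and induced in failing hearts, rose from 738 ± 125 to 1277 ± 39.3 CPM (SD, n = 3, log2 fold change 0.79, SE 0.17, adjusted p = 0.00183). The linked pair Mir221 (116 ± 28.6 to 255 ± 40.2 CPM, adjusted p = 0.000955) and Mir222 (47.1 ± 2.42 to 153 ± 30.9 CPM, adjusted p = 3.53e-05), named after their values were seen, rose too. Among the 4 planned scalings Mir221 lost its call only with snoRNA-based factors (adjusted p = 0.209). Without a filter 11 of the 15 rose and with factors from snRNA and rRNA genes 12, with 0 lower in each. With total counts alone 5 rose and 2 fell, and with snoRNA-based factors 3 rose and 4 fell, and Mir199a-1 was at a log2 fold change of -0.05. By camera the list stood above the other genes (adjusted p = 0.00564, and adjusted p = 0.442 with an estimated correlation). The miRNA class as a whole did so too, so camera does not set the list apart from other miRNAs. With miRNA-based factors 6 of the 15 rose and 0 fell (median 0.58). Mir208b, from an intron of the fetal myosin gene Myh7, rose from 10.5 ± 2.43 to 18.2 ± 6.10 CPM (log2 fold change 0.79, SE 0.29, adjusted p = 0.0399), with a value of -0.05 under snoRNA-based factors and no call with total counts alone (adjusted p = 0.215) or miRNA-based factors (adjusted p = 0.105). That call was lost without control replicate 2 (adjusted p = 0.0669) or 3 (adjusted p = 0.165), and without knockout replicate 1 the log2 fold change was 1.25. It was also lost by limma-voom (adjusted p = 0.0527) and against a fold change of 1.5 (edgeR adjusted p = 0.221). Its counterpart Mir208a, from the adult myosin gene Myh6, was not called (55.4 ± 5.63 and 43.3 ± 3.22 CPM, log2 fold change -0.35, SE 0.18, adjusted p = 0.128). It was called lower with total counts alone (-0.70, adjusted p = 0.0077), miRNA-based factors (-0.54, adjusted p = 0.0462) and snoRNA-based factors (-1.20, adjusted p = 0.000157).

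The heart and muscle miRNA miR-1 fell in both of its gene copies, which share their mature sequence and therefore their reads. Mir1a-1 went from 62248 ± 8787 to 41794 ± 5672 CPM (SD, n = 3; log2 fold change -0.57, SE 0.14, adjusted p = 0.0042). Mir1a-2 went from 62354 ± 6652 to 40728 ± 5470 CPM (log2 fold change -0.61, SE 0.13, adjusted p = 0.00183). Both calls were lost without knockout replicate 1 (adjusted p = 0.308 and 0.221), 2 (0.172 and 0.125) or 3 (0.0912 and 0.0644), where log2 fold changes were between -0.48 and -0.24. Values over all genes shifted upward in each of these fits, so the losses do not single out a mouse. Without a filter on low counts both calls were also lost, at -0.21 (adjusted p = 0.576) and -0.25 (adjusted p = 0.554). With factors from snRNA and rRNA genes neither Mir1a-1 (adjusted p = 0.998) nor Mir1a-2 (-0.04, adjusted p = 0.952) was called. With Mir208b these were the 3 called of 7 striated muscle miRNAs, 1 higher and 2 lower, also when adjusted over the list alone (median -0.44, camera adjusted p = 0.400). Without a filter 1 of 8 rose and 0 fell (median -0.06), and with factors from snRNA and rRNA genes 1 of 7 rose and 0 fell (median 0.15). By contrast 6 of 7 fell with total counts alone and with snoRNA-based factors. Of 6 members of the antifibrotic miR-29 and miR-30 families, Mir30e and Mir30c-1 fell and 0 rose, also when adjusted over the list alone (median -0.34, camera adjusted p = 0.308), and Mir30a was not called (log2 fold change -0.31, adjusted p = 0.0974). Without a filter 1 of the 6 rose, 0 fell and the median was 0.02, and with factors from snRNA and rRNA genes 0 were called (median 0.23). By contrast 5 fell with total counts alone and with snoRNA-based factors and 4 with miRNA-based factors. Mir30c-1 went from 3037 ± 323 to 2026 ± 152 CPM (log2 fold change -0.58, SE 0.15, adjusted p = 0.00576), a call lost without knockout replicate 1 (-0.35, adjusted p = 0.190), 2 (-0.29, adjusted p = 0.347) or 3 (-0.45, adjusted p = 0.106), and with factors from snRNA and rRNA genes (-0.02).

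Among 34 imprinted miRNAs of the Dlk1-Dio3 cluster 8 rose and 0 fell, but edgeR called 0 when adjusted over the list alone. The median of 0.48 became -0.36 with snoRNA-based factors. The list stood above the other genes by camera (adjusted p = 0.00166, and adjusted p = 0.442 with an estimated correlation), and with total counts alone 0 members were called. Those other genes include the pseudogenes and mitochondrial RNAs that fell. The miRNA class, in which 53 of 312 rose, passed camera as well (adjusted p = 0.00273). Camera therefore does not set this cluster apart from other miRNAs. With miRNA-based factors 1 of the 34 rose and 0 fell (median 0.30). Without a filter 17 of 41 rose, and with factors from snRNA and rRNA genes 23 of 34 (median 1.03). Its most abundant members were Mir127 (246 ± 21.1 to 346 ± 21.8 CPM, SD, n = 3, log2 fold change 0.50, SE 0.17, adjusted p = 0.0285, and -0.36 with snoRNA-based factors, with no call under total counts alone or miRNA-based factors) and Mir381 (log2 fold change 0.27, SE 0.24, adjusted p = 0.371, not called). The call of Mir127 was lost without control replicate 2 (adjusted p = 0.0776) or 3 (adjusted p = 0.0705), and its log2 fold change was 0.75 without knockout replicate 1. In the let-7 family 4 of 10 rose and 0 fell, also when adjusted over the list alone (median 0.26, or -0.08 with total counts alone, -0.59 with snoRNA-based factors and 0.80 with factors from snRNA and rRNA genes; camera adjusted p = 0.0684). With the preset correlation that list passed camera without control replicate 1 (adjusted p = 0.0245) or knockout replicate 1 (adjusted p = 0.0491). With all libraries and an estimated correlation its camera adjusted p was 0.682. The abundant members Mirlet7g (log2 fold change 0.17, SE 0.13, adjusted p = 0.301) and Mirlet7f-2 (0.11, SE 0.17, adjusted p = 0.613) were not called, and both were called lower with snoRNA-based factors.

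Whether markers of other heart cells were called depended on the scaling. The endothelial miRNA Mir126a was at 21503 ± 2131 CPM in control and 19692 ± 1811 CPM in knockout hearts (SD, n = 3; log2 fold change -0.13, SE 0.13, adjusted p = 0.424), and as the only tested member of its list it had no list test. It was called lower with total counts alone (-0.48, adjusted p = 0.00402), miRNA-based factors (-0.31, adjusted p = 0.0445) and snoRNA-based factors (-0.97, adjusted p = 0.000102), and was not called without a filter (0.22) or with factors from snRNA and rRNA genes (0.42). Of 4 smooth muscle and fibroblast miRNAs 2 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.455; median 0.27, or -0.07 with total counts alone and -0.57 with snoRNA-based factors), and the most abundant, Mir143, was not called (log2 fold change -0.20, adjusted p = 0.269). It was called lower under the same 3 scalings (-0.55, -0.39 and -1.05). Of 4 blood and immune miRNAs 1 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.490; median 0.45, or -0.40 with snoRNA-based factors). The red cell miRNA Mir451a (log2 fold change 0.40, SE 0.28, adjusted p = 0.258) and the leukocyte miRNA Mir142 (0.51, SE 0.22, adjusted p = 0.0751) were not called, though both were called higher without a filter (0.81 and 0.90) and with factors from snRNA and rRNA genes (1.08 and 1.13). Mir451a was called without knockout replicate 1 (0.83, adjusted p = 0.0136) or 2 (0.68, adjusted p = 0.0217), and Mir142 without knockout replicate 1 (0.79, adjusted p = 0.0117), 2 (0.84, adjusted p = 0.00632) or 3 (0.61, adjusted p = 0.0324).

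**Figure D4:**
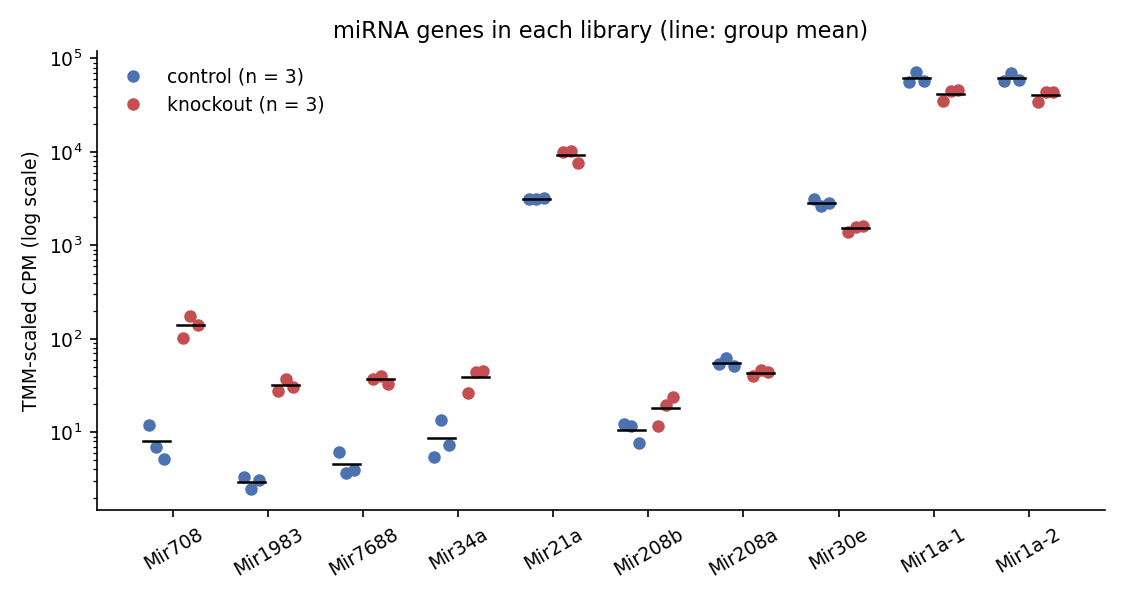
TMM-scaled CPM (log scale) of 10 miRNA genes in each control and knockout library (points, n = 3 per group; line, group mean). Mir708 went from a mean of 8.04 to 139 CPM and Mir21a from 3137 to 9356 CPM, both higher under each scaling tried, while the rise of Mir208b (10.5 to 18.2 CPM) turned to a log2 fold change of -0.05 with snoRNA-based factors.

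RNA polymerase III transcripts other than tRNA and 5S split. The 7SK RNA Rn7sk, which holds back the elongation factor P-TEFb, fell from 1522 ± 496 to 54.7 ± 17.5 CPM (SD, n = 3; log2 fold change -4.80, SE 0.33, adjusted p = 8.28e-07). The Y RNA Rny1, a partner of the Ro protein, fell from 1659 ± 326 to 378 ± 27.5 CPM (log2 fold change -2.14, SE 0.19, adjusted p = 4.11e-06). In total 6 of 9 tested members fell and 0 rose, while adjusted over the list alone 6 fell and 1 rose (median -1.18, camera adjusted p = 0.0486, and adjusted p = 0.442 with an estimated correlation). The RNase MRP RNA Rmrp (0.43, SE 0.18, adjusted p = 0.0691) and the RNase P RNA Rpph1 (0.14, SE 0.19, adjusted p = 0.577) were not called and were named after their values were seen. Rmrp was called higher without control replicate 1 (0.64, adjusted p = 0.00681), knockout replicate 2 (0.68, adjusted p = 0.0245) or knockout replicate 3 (0.67, adjusted p = 0.0208), and Rpph1 was called lower with snoRNA-based factors (-0.72), where Rmrp was at -0.43. Rmrp was also called higher with factors from snRNA and rRNA genes (0.94). The camera call was lost without control replicate 3 (adjusted p = 0.0589), knockout replicate 1 (adjusted p = 0.0502) or knockout replicate 2 (adjusted p = 0.0628), and with total counts alone (adjusted p = 0.0506). Malat1 (log2 fold change -0.47, SE 0.27, adjusted p = 0.174) and Neat1 (-0.18, SE 0.27, adjusted p = 0.593), nuclear RNAs with a tRNA-like 3′ end, were not called. However, snoRNA-based factors called both lower (-1.30 and -1.02) and total counts alone called Malat1 lower (-0.83, adjusted p = 0.0204). Annotated misc_RNA genes overlap exons of both on the same strand, so the reads of Malat1 and Neat1 are uncertain. Of 45 small nuclear RNA genes 24 fell and 0 rose, also when adjusted over the list alone, with a median of -0.93 (camera adjusted p = 0.000247, and adjusted p = 0.597 with an estimated correlation). With snoRNA-based factors 41 of them fell, with factors from snRNA and rRNA genes 9 fell and 3 rose, and without a filter 16 of 342 fell. Without knockout replicates 1, 2 and 3 the small nuclear RNA genes called lower were 23, 20 and 18, with medians of -0.903, -0.662 and -0.529. Of 77 nuclear rRNA genes 15 fell and 2 rose (2 and 1 adjusted over the list alone; camera adjusted p = 0.00564, and adjusted p = 0.682 with an estimated correlation). Their median was -0.53, or 0.02 with factors from snRNA and rRNA genes, which gave 2 lower and 10 higher. Under the planned scalings more were lower: 34 with DESeq2 size factors, 51 with total counts alone, 33 with miRNA-based and 74 with snoRNA-based factors. Without a filter 2 of 173 were lower. The camera call of the rRNA genes was lost without control replicate 3 (adjusted p = 0.0608) or knockout replicate 3 (adjusted p = 0.114).

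Nearly all pseudogenes that passed the filter on low counts fell: 106 of 110 were lower and 0 higher (107 and 0 adjusted over the list alone), among them 90 of 93 processed pseudogenes, with a median log2 fold change of -3.88, or -3.87 with genes at 0 counts in a group set to a floor of 3 counts over the group. Gm13910, which resembles the mRNA of the fatty acid oxidation gene Hadhb, went from 19.97 ± 9.70 to 0.302 ± 0.130 CPM (SD, n = 3; log2 fold change -6.01, SE 0.53, adjusted p = 4.23e-06). Without the filter 457 of 3344 processed pseudogenes were called lower and 0 higher by edgeR (median -2.17), and 318 of 3344 lower by DESeq2 (median -1.47). Of the 90 lower calls 89 were made with factors from snRNA and rRNA genes. The reads of Gm13910 are uncertain, since they can come from Hadhb itself, which was not analysed here. Iglj2, a 38 nt immunoglobulin segment that overlaps an exon of Iglc2, went from 16.4 ± 0.773 to 0.381 ± 0.165 CPM (log2 fold change -5.41, SE 0.32, adjusted p = 4.51e-07). Without control replicate 1, which had fewer pseudogene reads than the other controls, 258 processed pseudogenes were tested and 255 fell. Without knockout replicates 1, 2 and 3 there were 260, 259 and 261 tested and 233, 232 and 233 that fell. The knockout libraries, in which these genes were lower, also had fewer features with a count.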

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

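The tests in this part were planned before the data were examined, except the scaling by snRNA and nuclear rRNA genes, chosen after the results were seen. The count of 574 changed genes was 588 with DESeq2 size factors, 602 with total counts alone, 546 with miRNA-based factors, 760 with snoRNA-based factors, 633 with factors from snRNA and rRNA genes, 856 by DESeq2's Wald test, 568 by limma-voom, 418 against a fold change of 1.5 and 1141 without a filter on low counts, where 9254 genes were tested. Leaving out 1 library gave 486 to 908 changed genes, 54 to 106 miRNAs, 22 mitochondrial tRNAs each time, 11 to 13 mitochondrial mRNAs and rRNAs, 116 to 155 nuclear tRNAs, 117 to 172 snoRNAs and scaRNAs, and 11 to 13 lists by camera. The count of 73 miRNA genes was 169 with snoRNA-based factors (13 higher), 124 with factors from snRNA and rRNA genes (120 higher), 121 without a filter and 25 against a fold change of 1.5, and the 150 snoRNA and scaRNA genes were 96 against that fold change, which asks for larger effects. It also ended the calls of Mir149, Mir1a-1, Mir1a-2, Mir30c-1, Mir127, Mir199a-1, Mir208b, mt-Rnr1, mt-Rnr2, Gm24119, Snhg12, Gm26917 and the 3 Mir378 genes. Summed per anticodon, 53 nuclear tRNA forms were called in place of 120 features, since fewer units were tested. With an estimated correlation, 0 lists passed by camera in place of 13. With snoRNA-based factors the log2 fold changes of Mirlet7f-2 (-0.75), Mirlet7g (-0.68), Mir127 (-0.36), Mir199a-1 (-0.0492) and Mir208b (-0.0484) turned negative, and with factors from snRNA and rRNA genes those of Mir1a-1 (0.00108) and Gm24119 (0.0305) turned positive. The difference in the ribozyme share, 0.00204 percentage points, was -0.00175 without mitochondrial genes in the total, 0.00676 without control replicate 1, -0.00221 without control replicate 2 and -0.00305 without knockout replicate 1. For the scalings, the filter and these differences the cause was not tested. Of 752 values of named genes under all alternatives, 639 kept direction and side of the threshold, 53 lost a call, 25 gained one and 35 changed sign, 28 of them in genes called in neither fit. With the replicate number as a block (replicate block), 536 genes, 59 miRNAs, 22 mitochondrial tRNAs, 117 nuclear tRNAs, 145 snoRNAs and scaRNAs and 13 mitochondrial mRNAs and rRNAs were called. In that fit Mir127 and Gm24119 (adjusted p = 0.113 by edgeR for each), Snhg12 (adjusted p = 0.0551 by edgeR) and, by camera, the mature tRNA class (adjusted p = 0.0649) and the RNA polymerase III list (adjusted p = 0.0537) were not called. Same-numbered libraries did not deviate together (correlations -0.134, -0.0163 and -0.192), and no library correlated best with its own number. These values gave no sign that the numbers pair the mice, but a weak shared effect could go unseen. At this depth the simulated data gave, over all genes, 13 of 62 recovered changes of 1.5-fold.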

Other observations

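Every test in this part was chosen after the result was seen, except the pseudogene match, the snoRNA length test and the count of better-counted precursors. The sums per anticodon and the 4 planned scalings were set beforehand, but their use as tests of an explanation was chosen afterwards. A pair of neighbouring miRNA genes, best known from the exocrine pancreas, rose from near silence. Mir217 had 6 counts over the 3 control hearts and 226 over the 3 knockout hearts (log2 fold change 5.52, SE 0.36, adjusted p = 6.05e-07 by edgeR), and Mir216b had 0 and 125, at least 54.0-fold higher against a floor of 3 counts over the group (adjusted p = 6.32e-06 by edgeR). Of 4 tested Mir378 genes, 3 fell: Mir378a, encoded in the metabolic regulator gene Ppargc1b, went from 13994 ± 672 to 9284 ± 1014 CPM (SD, n = 3; log2 fold change -0.59, SE 0.13, adjusted p = 0.00215), Mir378c changed by -0.68 and Mir378d by -0.78, while Mir378b was not called (-0.26, adjusted p = 0.240 by edgeR). The 3 calls were lost without a filter on low counts (edgeR adjusted p = 0.554, 0.439 and 0.246). They were also lost without knockout replicate 1 (edgeR adjusted p = 0.244, 0.160 and 0.105) or 2 (0.222, 0.122 and 0.0693), and those of Mir378a and Mir378c without 3 (0.0725 and 0.0594). These genes were picked after their values were seen, and with factors from snRNA and rRNA genes Mir217 and Mir216b stayed called while the 3 Mir378 genes did not.

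Among other RNA polymerase III products, the Y RNA Rny3 fell from 783 ± 256 to 64.7 ± 19.7 CPM (SD, n = 3; log2 fold change -3.60, SE 0.32), the vault RNA Vaultrc5 from 40.8 ± 17.4 to 14.4 ± 1.38 CPM (log2 fold change -1.51, SE 0.31) and the 7SL RNA Rn7s1 from 124 ± 31.8 to 54.6 ± 2.48 CPM (log2 fold change -1.18, SE 0.21). Of the spliceosomal RNAs, Rnu1a1 went down (log2 fold change -1.09, SE 0.28, adjusted p = 0.00654 by edgeR), while the histone processing RNA Rnu7 was not called (0.19, SE 0.20, adjusted p = 0.449 by edgeR; -0.65 and called lower with snoRNA-based factors). Without knockout replicate 3 the log2 fold change of Rnu1a1 was -0.67, and with factors from snRNA and rRNA genes it was not called (edgeR adjusted p = 0.0615) while Rnu7 was called higher (0.75). Among the pseudogenes that fell were Gm5436, which resembles the ATP synthase gene Atp5o (log2 fold change -4.93), and Fabp3-ps1, which resembles the fatty acid carrier gene Fabp3 (-4.37). The lincRNA genes Snhg12 (log2 fold change 0.66, adjusted p = 0.0130 by edgeR) and Gm26917 (0.43, adjusted p = 0.0413 by edgeR) and the misc_RNA gene Gm26461 (0.65, adjusted p = 0.0463 by edgeR) were called higher, but none of them with total counts alone, miRNA-based or snoRNA-based factors. These genes were also picked after their values were seen.

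Reads from mitochondrial mRNAs, 7SK and pseudogenes, which are longer than the size window, were lower in knockout hearts, as were 8 of 15 lincRNA genes (2 higher, median log2 fold change -1.08) and 14 of 20 misc_RNA genes (1 higher, median -2.01), while Malat1, Neat1, Rmrp and Rpph1 were not called. Library scaling cannot change their ratios to mitochondrial rRNA counts within a library, and the lowest control ratio was at least 3.40 times the highest knockout ratio (3.40 for pseudogenes, 4.87 for mitochondrial mRNA and 10.8 for 7SK), so scaling alone is argued against. Long RNAs did not fall alike: mt-Rnr1, the lowest of mt-Rnr1, mt-Rnr2, Rmrp and Rpph1, lay 1.44 (SE 0.33) above mt-Co3, the highest mitochondrial mRNA. These comparators were picked when their smaller changes were already known. The gap therefore shows only that the falls were unequal, and it cannot decide whether fragmentation was reduced. Mitochondrial reads placed on nuclear pseudogenes cannot account for the fall, as 0.943% of the 106 lower pseudogenes matched a mitochondrial gene while 97.2% matched a protein-coding transcript. A lower supply of mRNA fragments in knockout hearts, from either less mRNA or less breakage of some RNAs before library preparation, may remain, and nuclear mRNA levels and RNA integrity were not analysed here.

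The ratio of snoRNA and scaRNA to miRNA counts within a library went from 0.987 ± 0.0539 to 2.01 ± 0.174 (SD, n = 3 per group; exact permutation p = 0.1, the smallest possible), a ratio that no scaling can change, and the lowest knockout ratio was 1.78 times the highest control ratio. A library preparation that kept longer inserts in knockout hearts might raise snoRNAs over miRNAs, with larger rises for longer snoRNAs. Across 160 snoRNAs of up to 100 nt Spearman's rho was -0.072 (permutation p = 0.367) and Pearson's r was -0.0733 (permutation p = 0.356), and genes are not independent replicates. A rho at or below 0 had been set beforehand as speaking against it, but this one is too close to 0 to decide; 82 longer snoRNAs had a median log2 fold change of 0.10, against 1.09 for the 160. Whether snoRNAs rose or miRNAs fell per cell stays open, as does a biological effect of the knockout.

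In the main fit 43 of 114 precursor tRNAs rose and 14 fell, while 48 of 124 mature tRNAs fell and 15 rose. Loss of an enzyme that trims tRNA 3′ ends could bring about such a split. In the main scaling the sums per anticodon gave 21 higher and 4 lower precursor anticodons. Splitting of reads between near-identical copies within a form is argued against by these sums. They kept mature and precursor features apart, so they cannot show whether reads of one form were counted for the other. Scaling cannot change the precursor to mature ratio within a library (0.0110 ± 0.000609 to 0.115 ± 0.0285, SD, n = 3), whose lowest knockout value was 7.08 times the highest control value, but that ratio moved mostly through the fall of mature forms (7.39 times lower share). The most abundant mature anticodons in control hearts were Gly-CCC (16699 CPM, log2 fold change -2.59), Glu-CTC (5345 CPM, -4.18) and Gly-GCC (3586 CPM, -2.72). These anticodons weigh most in the ratio, which therefore says little about the others. Their reads may come from whole tRNAs or from fragments, which the counts do not tell apart. For the rise of precursors themselves scaling stays open, with a lowest median of -0.64 under 4 other scalings (and for mature forms, with a median of 0.09 under factors from snRNA and rRNA genes), and so do low counts: of the 9 precursors with at least 10 CPM, 2 rose and 3 fell, so the excess of higher precursors may rest on rarely counted features. A biological cause is therefore a hypothesis for the ratio, not for a rise of precursors or a fall of mature forms as a class.

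A further hypothesis is that mitochondrial tRNAs of the light strand depend more on RNase Z. The mean log2 fold change was -4.46 ± 1.57 (SD) for the 8 light-strand and -2.96 ± 1.32 for the 14 heavy-strand tRNAs, a difference of -1.50 (exact two-sided permutation p = 0.0274). These genes are not independent replicates, and the difference was tested on the same values in which it was noticed, so it may not hold in other hearts. Reads within the size window also cannot tell a loss of tRNA from tRNA left in longer transcripts.

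The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05, and the real split was the 1 of 10 with as many calls in each case. It gave 574 changed genes, 73 miRNAs, 22 mitochondrial tRNAs, 120 nuclear tRNAs, 150 snoRNAs and scaRNAs and 13 mitochondrial mRNAs and rRNAs, and the highest other split gave 0 for each by edgeR, with at most 23 genes at an unadjusted p under 0.05, against 659 in the real split. Each other split put knockout and control libraries on both sides, which widens the spread within its groups. Few calls were therefore to be expected there, and the contrast does not measure chance.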
